A study of Mus musculus with 8 samples.

How the data were processed

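The data are a table of counts per gene from RNA-seq of tibiae and femurs spun to remove marrow. The bones came from 8 mice, 4 given saline vehicle and 4 given doxorubicin at 10 mg/kg, killed on day 30. Per the labels' protocols, bones were cleaned of soft tissue, their ends were cut off, marrow was spun out, and both tibiae and femurs of a mouse gave 1 RNA sample, so replicates are separate animals. Libraries were made with a stranded poly-A kit from 500 ng of RNA, with adaptors carrying unique molecular identifiers and 15 cycles of PCR, per the labels' protocols. Whether the identifiers were used to remove duplicate reads is not given in the sources used here, so reads are not taken as independent molecules.

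The unit of the deposited values was taken to be expected counts; all are whole numbers, so rounding them before the tests changed nothing. The submitters' processing notes name STAR 2.5.3a, an aligner, and RSEM 1.3.0, which estimates expected counts and divides reads between genes they fit equally well. The role of each tool and any rounding are not given in the sources used here. The same notes name the genome build GRCh38, which is human, whereas the identifiers in the table are those of mouse genes. The annotation release, the use of strand and any filter are not given in the sources used here. Of the 55421 identifiers, 54587 matched the GENCODE M21 annotation of GRCm38 with their version and 55154 without it. That annotation was used only to give positions. Symbols came from the deposited table, and 45 tested genes whose symbol belonged to several identifiers were kept under the identifier.

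Genes with near-identical copies may share or lose reads: the haemoglobin alpha and beta pairs, Bglap and Bglap2, and nuclear copies of mitochondrial genes, which took between 6.55% and 11% of counts in a library. Gm42418, which overlaps ribosomal RNA, took between 0.904% and 3.09%. Library totals ran from 23699525 to 35747083 counts, and the number of mice, not depth, set most of the precision for well expressed genes. The biological coefficient of variation estimated by edgeR was 0.219. All 8 columns were matched to samples by the labels. Over the 28 pairs of libraries, chi-square per degree of freedom lay between 29.0 and 297, so no 2 libraries agreed within sampling noise.

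Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17035, and were scaled by TMM. The main test was edgeR's robust quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, with no block or covariate. CPM values are scaled by TMM, with mean ± SD over the 4 mice of a group. Log2 fold changes are doxorubicin over vehicle, and their SE was derived from the quasi-likelihood F statistic. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, and an adjusted p that DESeq2 left undefined (1982 genes) was not counted. The median log2 fold change of all tested genes was 0.04.

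A total of 35 gene lists for complement, senescence, bone cells, marrow and other cells, and handling were fixed before the data were examined, as were the main tests, most alternatives and the rule for naming genes. Lists were tested against all other genes with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the lists. Camera with a correlation estimated from each list was an alternative form of the same test. Fry, which tests whether the genes of a list move on balance in 1 direction, and an exact permutation test of the mean log CPM of each list over 70 arrangements of the libraries were also run; both have another null hypothesis, since neither compares a list with other genes. The count of members past the threshold was adjusted over all genes and over the list alone. Members of a list can vary together, so the number above or below 0 is not a number of separate observations. Ahsp, of the erythroid list, was not matched by symbol and is not analysed here. Library composition was compared by two-sided exact permutation tests of 7 measures.

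The rule named up to 10 genes higher and 10 lower among those past the threshold with a mean of at least 1 CPM and groups that did not overlap, which gave 0 genes. It also named up to 4 members of each list with the smallest p, of which the text gives a part, and a fixed set (Cdkn1a, Cdkn2a, C3, C3ar1, C5ar1, Cfd, Tnfsf11, Tnfrsf11b, Acp5, Ctsk, Sost, Col1a1 and Bglap). Further genes are said to have been named after their values were seen.

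The alternatives changed 1 choice at a time: DESeq2 size factors in edgeR, library size as the only scaling, haemoglobin genes left out, no filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, a covariate for residual marrow (the mean log CPM of the neutrophil and erythroid lists), an adjusted p threshold of 0.1 and each replicate left out in turn. Leaving out mitochondrial genes, a muscle covariate and the permutation of list scores were chosen after seeing the data. All 35 splits of the 8 libraries into 4 and 4 were refitted. The tests were tested on simulated data, made from the means, dispersions and library sizes of the 17035 genes with 200 genes changed. In the simulation edgeR called 10 unchanged genes, DESeq2 35 and limma-voom 6. DESeq2 recovered 34% of 1.5-fold and 82% of 2-fold changes, and limma-voom 14% and 74%. These shares come from genes simulated to vary independently, so they may not hold in the real libraries. Camera called a list of 20 genes shifted by 1.5-fold and 0 of 30 unshifted lists, but the simulated genes varied independently, unlike genes of 1 cell type. Figures were drawn with matplotlib 3.10.9.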

Results

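Polyadenylated RNA was sequenced from the hindlimb long bones of 8 male C57BL/6 mice aged 15 weeks at the start. The tibiae and femurs were spun to remove marrow, and their ends were cut off. Of the mice, 4 were given saline and 4 a single intraperitoneal dose of 10 mg/kg doxorubicin, a chemotherapy drug that damages DNA. Bones were taken on day 30, and each library came from 1 mouse. The deposited table held 55421 genes, of which 24934 had no count in any library, and the libraries held between 23699525 and 35747083 counts. The series uses the drug to model senescence brought on by chemotherapy, and its title names complement, osteoclast precursors and bone loss. The comparison therefore asked how complement genes, senescence genes and the genes of bone-forming, bone-resorbing and marrow cells differed between the doxorubicin and vehicle bones.

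Spearman correlations of log CPM lay between 0.970 and 0.988 within the vehicle group, between 0.972 and 0.988 within the doxorubicin group, and between 0.957 and 0.990 across the groups. Haemoglobin genes took 2.64% ± 1.03 (SD, n = 4) of counts in vehicle and 1.93% ± 0.806 (SD, n = 4) in doxorubicin bones. Skeletal muscle genes took 2.78% ± 1.37 and 3.42% ± 1.24 (SD, n = 4 each), with vehicle 3 the lowest at 0.733%. Mitochondrial mRNAs took 16.6% ± 3.64 and 18.0% ± 3.49, and immunoglobulin genes 0.12% ± 0.0443 and 0.0754% ± 0.0166 (SD, n = 4 each). Marrow RNA was still present in the spun bones. Mean log2 CPM in vehicle was 8.17 for neutrophil and 8.56 for erythroid genes, against 7.05 for osteoblast and 4.47 for osteocyte genes. These list means do not give shares of cells. None of the 7 library measures passed the threshold between the groups, with adjusted p between 0.767 and 0.857 in exact permutation tests, which cannot go below 0.0286 before adjustment with 4 mice against 4. The first principal component held 34.3% of the variance and placed vehicle 3 and doxorubicin 1 at its ends. It correlated at −0.94 with the mean log CPM of the skeletal muscle list and at 0.67 with that of the neutrophil list. Its group difference had an exact permutation p of 0.371.

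Cyp2e1, a cytochrome P450 enzyme that oxidises ethanol and other small molecules, had the smallest p of all genes. It stood at 1.24 ± 0.402 CPM in vehicle and 4.51 ± 0.786 CPM in doxorubicin bones (SD, n = 4 each), a log2 difference of 1.86 ± 0.24 (SE). Its adjusted p was 0.326 in edgeR's quasi-likelihood test and 6.8e-08 in DESeq2. It was named after its values were seen. In edgeR, 0 of 17035 tested genes were higher and 0 were lower in doxorubicin at an adjusted p under 0.05, while 913 had an unadjusted p under 0.05 against 852 expected by chance, 362 of them higher and 551 lower. On the same genes the 913 became 1784 without vehicle 4, 1318 without doxorubicin 3 and 1185 with the marrow covariate, but 686 with library size as the only scaling, 632 without vehicle 2 and 621 without doxorubicin 4, and between 749 and 881 without any other library. DESeq2 placed 7 genes higher and 22 lower, and limma-voom placed 0 past the threshold. All 29 DESeq2 genes had groups that did not overlap, as did 612 of all tested genes (3.59% against 2.86% by chance). With no filter on low counts edgeR called 1 gene, Cyp2e1, at an adjusted p of 0.0280; over the other settings of edgeR, libraries left out included, its adjusted p lay between 0.0915 and 1.00. In counts simulated for the same genes and libraries, edgeR recovered 14% of 1.5-fold, 74% of 2-fold and 92% of 4-fold changes. A small change in a single gene was therefore mostly not detectable here. The simulated genes varied independently, unlike genes of 1 cell type, so the shares for 2-fold and 4-fold changes may not hold in the real libraries. There the main edgeR test did not call Cyp2e1, at a log2 difference of 1.86. The lack of calls therefore does not show that larger changes were absent.

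**Figure D1:**
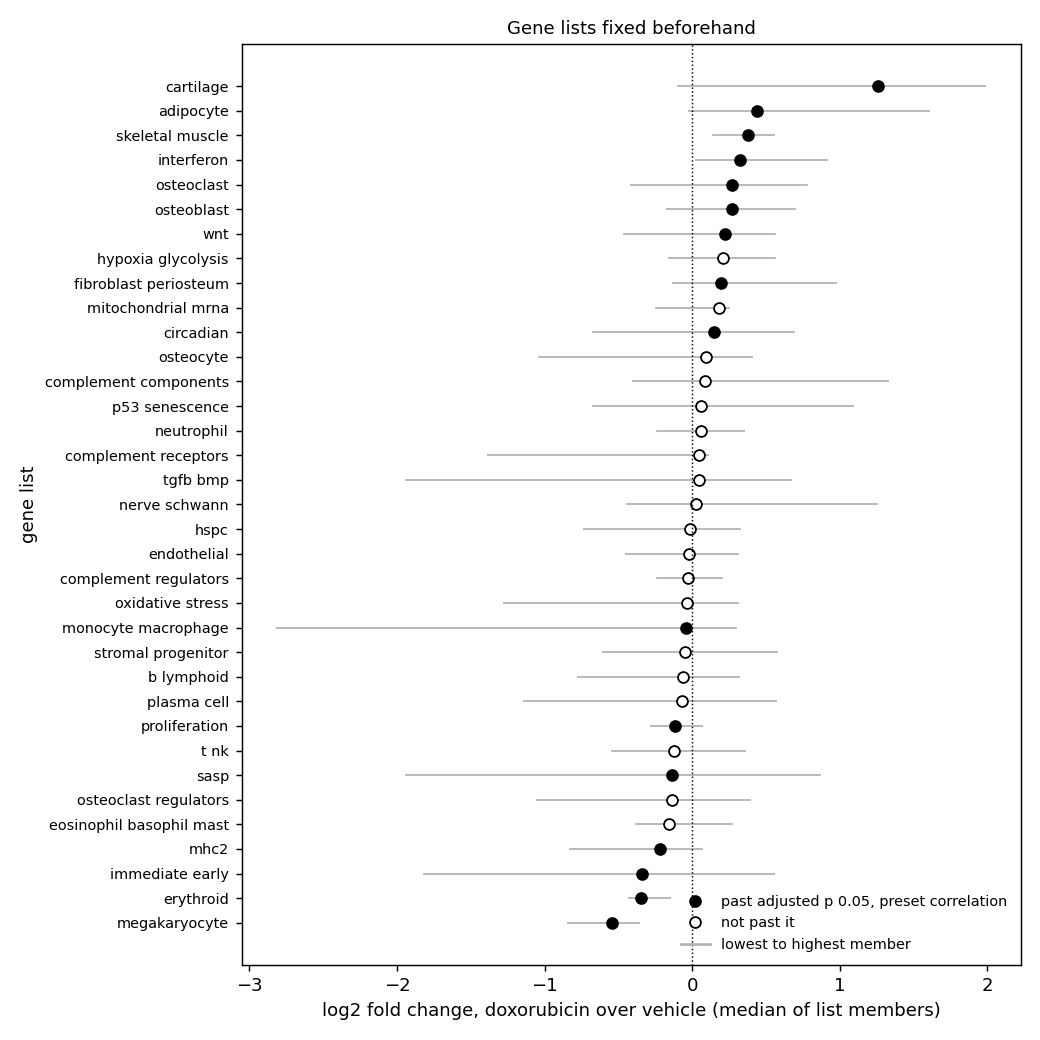
Median log2 fold change (doxorubicin over vehicle, 4 mice each) of the tested members of each of 35 gene lists, with a grey line from the lowest to the highest member. Filled circles passed an adjusted p of 0.05 in camera with a preset correlation, and none passed with an estimated correlation; the medians ran from −0.54 for megakaryocyte genes to 1.26 for cartilage genes.

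Among complement components, Cfd (complement factor D, the serine protease of the alternative pathway, which fat cells secrete as adipsin) had the smallest p. It measured 15.6 ± 3.25 CPM in vehicle and 39.2 ± 21.3 CPM in doxorubicin bones (SD, n = 4 each), a log2 difference of 1.33 ± 0.32 (SE), and each doxorubicin library lay above each vehicle library. Without doxorubicin 2 the difference was 0.84. The list of adipocyte genes, which does not hold Cfd, was also higher in camera with the preset correlation (adjusted p = 0.000272; adjusted p = 0.697 with an estimated correlation). Doxorubicin 2 had the highest CPM of Cfd (70.9) and of the fat-cell genes Plin1 (8.95) and Cidec (8.38), whose log2 differences without that library were 0.81 and 0.78. Adipoq (adiponectin), chosen after its values were seen, had a log2 difference of −0.02 ± 0.28 (SE). C3, the central component cleaved in all complement pathways, was at 138 ± 8.13 and 149 ± 35.3 CPM. Its receptor C3ar1 was at 8.45 ± 1.03 and 8.73 ± 1.53 CPM, and the C5a receptor C5ar1 at 20.0 ± 2.84 and 21.6 ± 1.76 CPM (SD, n = 4 each). Of the 20 tested components, 12 lay above and 8 below 0, and their median log2 fold change was 0.09. C7, a part of the membrane attack complex, had a log2 difference of 0.87 ± 0.46 and C1qa, which starts the classical pathway, one of −0.32 ± 0.19 (SE). Vsig4, a complement receptor of tissue macrophages, measured 1.89 ± 1.48 and 0.733 ± 0.257 CPM (SD, n = 4 each). Without doxorubicin 1 the log2 difference of C7 was 0.28, and without vehicle 3 that of Vsig4 was −0.84 and that of C1qa −0.21. The complement lists were fixed before the data were examined, but complement is named in the title of the series. That title may itself rest on these samples, so the lists are not independent evidence.

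Cfd was the 1 complement component past the threshold when adjusted over the list alone (adjusted p = 0.0476 in edgeR), and 0 were past it over all genes tested, where its adjusted p was 0.703. DESeq2 gave Cfd an adjusted p of 0.0383. In camera with the preset correlation the components had an adjusted p of 0.374, the receptors 0.690 and the regulators 0.463. The 8 receptors had a median of 0.05 but a mean of −0.13, and the test pointed lower. The 9 regulators had a median of −0.03, with Serping1 (the C1 inhibitor) at 0.21 ± 0.13 and Csmd1 at −0.24 ± 0.19 (log2 ± SE). Serping1 was at 0.13 without vehicle 2 and 0.11 without doxorubicin 2, and Csmd1 at −0.37 without vehicle 2 and −0.12 without vehicle 3. The call of Cfd over its list alone was lost without vehicle 1, 2, 3 or 4 or doxorubicin 4. It was also lost under DESeq2 size factors, library size as the only scaling, no filter, the marrow covariate and the replicate number as a block. Leaving out haemoglobin or mitochondrial genes lost it too. Without vehicle 3 the components list passed, with an adjusted p of 0.0181.

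**Figure D2:**
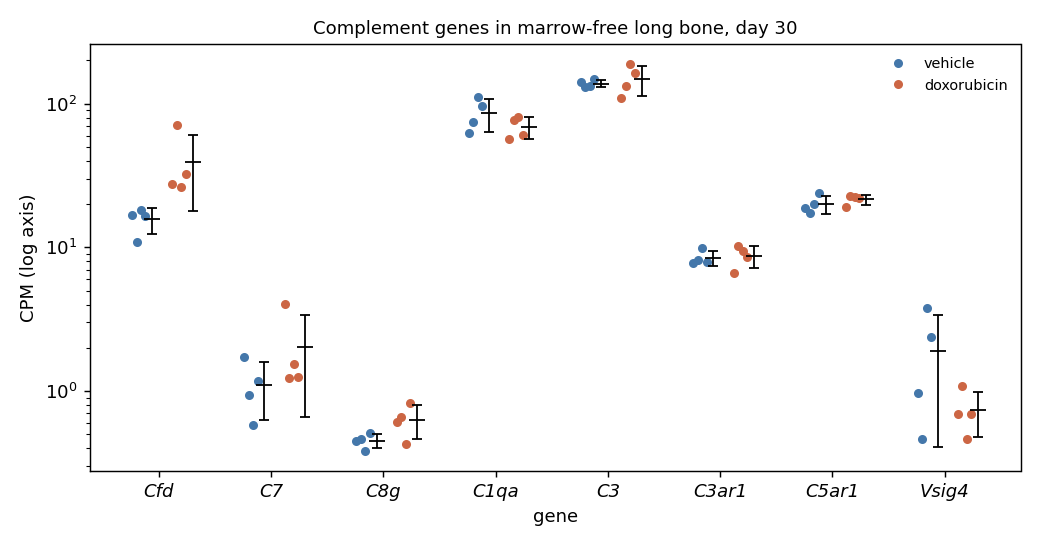
CPM on a log axis of 8 complement genes in each library (blue, 4 vehicle mice; orange, 4 doxorubicin mice), with black bars for mean ± SD. Cfd is the gene whose groups are fully separate, while C3, C3ar1 and C5ar1 overlap.

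Senescence genes as a group did not pass the test. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 34.0 ± 19.6 CPM in vehicle and 29.1 ± 12.4 CPM in doxorubicin bones (SD, n = 4 each). Cdkn2a, which encodes p16, was at 0.304 ± 0.118 and 0.493 ± 0.153 CPM (SD, n = 4 each), a log2 difference of 0.63 ± 0.36 (SE). Eda2r, a death receptor gene activated by p53, was at 7.81 ± 3.84 and 16.5 ± 4.69 CPM, and Phlda3, another p53 target, at 32.2 ± 11.3 and 51.9 ± 19.1 CPM (SD, n = 4 each). Of the 25 genes of the p53 and senescence list, 14 lay above and 11 below 0, and 0 passed the threshold, whether adjusted over the list alone or over all genes. Camera gave this list an adjusted p of 0.463. Of the 32 tested genes of the secretory phenotype of senescent cells, 20 lay below 0. Il1a had a log2 difference of −0.66 ± 0.20, Il6 of −1.05 ± 0.40 and the matrix protease Mmp3 of 0.87 ± 0.29 (SE). Camera placed the list lower at an adjusted p of 0.0436 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. The call was lost without vehicle 1 (0.152), vehicle 3 (0.238), doxorubicin 1 (0.289) or doxorubicin 3 (0.104), without haemoglobin genes (0.0559) or mitochondrial genes (0.0639), with the 1 CPM filter (0.0516) and with the muscle covariate (0.175), and 0 members passed over the list alone. Without vehicle 1 the log2 difference of Il6 was −0.67, and that of Cdkn1a, −0.22 with all libraries, was 0.18 and between −0.49 and −0.03 with any other library left out. That of Cdkn2a was 0.41 without vehicle 2 and 0.42 without doxorubicin 1, and that of Phlda3, 0.69 with all libraries, was 0.41 without vehicle 3 and 0.40 without doxorubicin 1.

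Osteoclast genes lay on the higher side in doxorubicin bones. Of the 18 genes, 14 were above 0, and the median log2 fold change was 0.27. Calcr, the calcitonin receptor, was at 1.88 ± 0.458 CPM in vehicle and 3.24 ± 0.894 CPM in doxorubicin (SD, n = 4 each). Oscar, a co-receptor of osteoclast formation, was at 4.30 ± 1.37 and 6.84 ± 0.716 CPM, and Dcstamp, needed for the fusion of osteoclast precursors, at 4.58 ± 1.60 and 7.19 ± 0.907 CPM (SD, n = 4 each). Acp5 (tartrate-resistant acid phosphatase) had a log2 difference of 0.41 ± 0.27 and the collagen-degrading Ctsk of 0.29 ± 0.28 (SE). Without vehicle 2 the difference was 0.18 for Acp5, 0.07 for Ctsk and 0.41, against 0.64 with all libraries, for Dcstamp, and without vehicle 3 it was 0.52 for Ctsk. Itgb3, an integrin that platelets share, went the other way at −0.41 ± 0.14 (SE). Camera placed the list higher at an adjusted p of 0.00216 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. Without vehicle 2 it was 0.0528. Over the list alone 0 of 18 osteoclast genes passed. The regulators of osteoclasts had a median of −0.14 and an adjusted p of 0.0922, which was 0.0133 without vehicle 4 and 0.0457 without doxorubicin 2. Among them Tnfsf11 (RANKL) was at 8.73 ± 3.71 and 7.19 ± 2.39 CPM, and its decoy receptor Tnfrsf11b at 15.5 ± 3.63 and 14.6 ± 4.04 CPM (SD, n = 4 each). Csf1 had a log2 difference of −0.45 ± 0.24 (SE), which was −0.17 without vehicle 1. With 1 library left out, the log2 difference of Tnfsf11, −0.28 with all, ran from −0.53 without vehicle 4 to 0.0061 without vehicle 1, and that of Tnfrsf11b, −0.083 with all, from −0.24 without vehicle 4 to 0.096 without doxorubicin 4.

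Osteoblast genes also had a median of 0.27, with 18 of 21 above 0. Pth1r, the parathyroid hormone receptor, measured 42.2 ± 9.98 and 61.4 ± 14.5 CPM, and the transcription factor gene Dlx5 7.64 ± 2.95 and 12.4 ± 3.26 CPM (SD, n = 4 each). Phospho1, which acts in mineralisation, had a log2 difference of 0.52 ± 0.27 (SE). Col1a1 was at 2281 ± 1023 and 3153 ± 2308 CPM (SD, n = 4 each), and Bglap (osteocalcin, which may share reads with its near-identical neighbour Bglap2) had a log2 difference of 0.34 ± 0.45 (SE). That of Bglap was −0.0045 without doxorubicin 1, −0.0041 with the marrow covariate and 0.72 without vehicle 1; that of Col1a1, 0.47 with all libraries, was −0.11 without doxorubicin 2, 0.22 without vehicle 2 and 0.73 without doxorubicin 4. Phospho1 was at 0.30 without vehicle 3. Camera gave the osteoblast list an adjusted p of 0.0257 with the preset correlation, and the adjusted p was 0.711 with an estimated correlation. It was 0.236 without vehicle 2, 0.779 without doxorubicin 1, 0.451 without doxorubicin 2, 0.678 with the marrow covariate and 0.0582 with the muscle covariate. Osteocyte genes had a median of 0.10 and an adjusted p of 0.649, which was 0.0407 without doxorubicin 4. Dmp1, made by osteocytes, was at 362 ± 242 and 176 ± 63.4 CPM, and Sost, which encodes sclerostin, at 72.0 ± 15.0 and 80.0 ± 37.4 CPM (SD, n = 4 each). The log2 difference of Dmp1 was −1.03, and −0.62 without vehicle 1, and that of Sost, 0.15, ran from −0.13 without doxorubicin 2 to 0.37 without doxorubicin 4. The Wnt list had a median of 0.22, with Wif1 at 0.54 ± 0.19 and Wnt5a at 0.52 ± 0.19 (SE). Its adjusted p was 0.00663 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation; it was 0.0566 without vehicle 2, 0.115 without doxorubicin 1 and 0.0706 with the marrow covariate.

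The megakaryocyte genes were the list with the smallest camera p. All 11 tested genes were lower in doxorubicin bones, with a median log2 fold change of −0.54. Gp6, the collagen receptor of platelets, was at 75.5 ± 16.7 CPM in vehicle and 44.9 ± 5.54 CPM in doxorubicin, Treml1 at 42.8 ± 3.94 and 29.6 ± 5.44 CPM, Thbs1 at 444 ± 131 and 248 ± 60.7 CPM and Gp5 at 35.4 ± 4.40 and 24.3 ± 5.65 CPM (SD, n = 4 each). Each of these 4 genes had groups that did not overlap. Over the list alone, 8 of the 11 passed the threshold in edgeR, Gp6 with an adjusted p of 0.0131, and 0 passed over all genes. The mean score of the list fell in an exact permutation test with the smallest p that 4 against 4 can give (p = 0.0286), which became 0.5 when adjusted over the 35 lists. Camera gave an adjusted p of 1.7e-15 with the preset correlation, and the adjusted p was 0.317 with an estimated correlation. The count of 8 became 1 without vehicle 2 or doxorubicin 4, 2 without doxorubicin 3, 4 without vehicle 4 or doxorubicin 1, 5 without vehicle 3, 2 with library size as the only scaling and 3 with residual marrow as a covariate, but 10 without vehicle 1 or doxorubicin 2 and 11 with no filter on low counts. The median log2 fold change was −0.59 with library size only and −0.46 with the marrow covariate, with camera adjusted p of 8.1e-14 and 1.7e-13, and lay between −0.65 and −0.42 with each library left out.

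**Figure D3:**
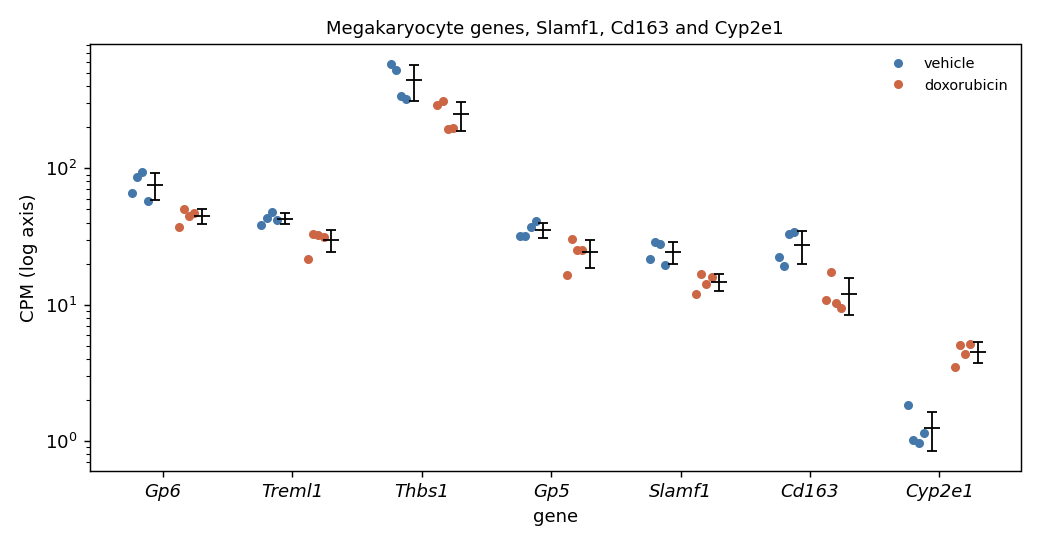
CPM on a log axis of 4 megakaryocyte genes, Slamf1, Cd163 and Cyp2e1 in each library (blue, 4 vehicle mice; orange, 4 doxorubicin mice), with black bars for mean ± SD. In each of these 7 genes the groups are separate, with Cyp2e1 the one that is higher in doxorubicin.

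All 16 tested erythroid genes were below 0 (median −0.35), with Hemgn at −0.37 ± 0.25 (SE), which was −0.71 without doxorubicin 3 and −0.25 without doxorubicin 4. Their camera adjusted p was 4.3e-05 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. That correlation between members was estimated at 0.84. The erythroid score had an exact permutation p of 0.257 before adjustment over the lists. Slamf1, a surface receptor that marks blood stem cells and is also found on lymphocytes and megakaryocytes, was at 24.5 ± 4.46 and 14.8 ± 2.12 CPM (SD, n = 4 each) and was the 1 stem and progenitor gene past the threshold over the list alone (adjusted p = 0.0130 in edgeR), with Hoxa9 beside it without doxorubicin 3. The stem and progenitor list itself had a camera adjusted p of 0.374. Neutrophil genes had a median of 0.06 while the test pointed lower, with an adjusted p of 0.690 (0.0135 without doxorubicin 3) and Cxcr2 at 0.18 ± 0.20 (SE), which was 0.10 without vehicle 1, 0.28 without vehicle 3 and −0.0035 without doxorubicin 3. B lymphoid genes had an adjusted p of 0.0922 and a median of −0.06, with 8 above and 10 below 0. Among them Ighm was at −0.77 ± 0.28 and Vpreb3 at 0.31 ± 0.23 (SE). Plasma cell genes had an adjusted p of 0.134 and a median of −0.07, with 5 above and 5 below 0. Jchain was at −1.13 ± 0.38, Ighg2c at −1.14 ± 0.37 and Igha at 0.57 ± 0.37 (SE). The adjusted p was 0.0594 for T and NK cell genes and 0.0940 for eosinophil, basophil and mast cell genes, with medians of −0.12 and −0.16. These lists passed the threshold in some alternatives: B lymphoid genes without vehicle 1 (0.0355), vehicle 2 (0.0117), doxorubicin 1 (0.0239) or doxorubicin 2 (0.00174), T and NK cell genes without vehicle 1 (0.0171), vehicle 4 (0.0480), doxorubicin 2 (0.00472) or doxorubicin 3 (0.0122), as also with the 1 CPM filter (0.0185), and the eosinophil list without vehicle 4 (0.000442) or doxorubicin 4 (0.0407). The 29 proliferation genes had a median of −0.12, 25 of them below 0, with Mki67 at −0.28 ± 0.24 (SE), −0.17 without doxorubicin 1 and −0.59 without doxorubicin 3. Their adjusted p was 0.00356 with the preset correlation, and the adjusted p was 0.711 with an estimated correlation; it was 0.0678 without vehicle 3, 0.818 without doxorubicin 1, 0.0567 without doxorubicin 2, 0.806 with the marrow covariate and 0.304 with the muscle covariate.

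In the monocyte and macrophage list, Cd163, Marco and Mertk had the smallest p. Cd163, the haemoglobin scavenger receptor, was at 27.2 ± 7.45 CPM in vehicle and 12.0 ± 3.61 CPM in doxorubicin bones (SD, n = 4 each), a log2 difference of −1.18 ± 0.24 (SE). It was the 1 of 20 members past the threshold over the list alone in edgeR (adjusted p = 0.0138). The call was lost without doxorubicin 1 or doxorubicin 4, with the marrow covariate and with the replicate number as a block. Without vehicle 2, Marco and Mertk passed with Cd163. Over all genes the adjusted p of Cd163 was 0.703 in edgeR and 0.00845 in DESeq2. Marco, a scavenger receptor, was at 2.85 ± 3.02 and 0.392 ± 0.191 CPM (SD, n = 4 each), and Mertk, a receptor for apoptotic cells, had a log2 difference of −0.41 ± 0.17 (SE). The median of the whole list was −0.04, with 9 members above and 11 below 0. Camera gave an adjusted p of 0.0406 with the preset correlation, and the adjusted p was 0.707 with an estimated correlation. With the preset correlation it was 0.550 without vehicle 3, 0.779 without doxorubicin 1, 0.0543 without doxorubicin 4 and 0.0707 with the 1 CPM filter. It was 0.671 with the marrow covariate, 0.588 with the muscle covariate and 0.065 with the replicate number as a block. Genes of MHC class II antigen presentation had a median of −0.22, with 13 of 14 below 0. Among them the costimulatory Cd80 was at 8.0 ± 2.53 and 4.49 ± 0.377 CPM and Cd86 at 15.0 ± 2.84 and 11 ± 0.978 CPM (SD, n = 4 each). Their adjusted p was 9.8e-05 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation.

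All 26 interferon-response genes were above 0, with a median log2 fold change of 0.32. Oas2 and Oasl2, of the family of antiviral oligoadenylate synthetases, were at 17.6 ± 1.83 and 19.7 ± 2.73 CPM in vehicle and at 29.1 ± 7.49 and 37.1 ± 13.5 CPM in doxorubicin bones (SD, n = 4 each). Ifi44 had a log2 difference of 0.74 ± 0.23 (SE). The list had a camera adjusted p of 7.4e-10 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. That correlation between members was estimated at 0.71. The interferon score had an exact permutation p of 0.114 before adjustment over the lists. Over the list alone 0 members passed in edgeR, with Oas2 at an adjusted p of 0.0508. Without doxorubicin 3 the median was 0.18.

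Cartilage genes had the highest median, 1.26, with 14 of 15 above 0. Comp, a cartilage matrix protein, was at 18.0 ± 7.54 and 31.0 ± 3.54 CPM, Prg4 (lubricin) at 16.9 ± 10.4 and 44.1 ± 28.5 CPM and Acan (aggrecan) at 2.71 ± 2.11 and 6.85 ± 5.95 CPM (SD, n = 4 each). The log2 difference of Acan was 1.34 with all libraries, 0.50 without doxorubicin 3 and 2.02 without vehicle 1, and that of Prg4 was 1.38 and, without doxorubicin 1, 0.89. The adjusted p was 5.4e-05 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. Adipocyte genes had a median of 0.44, with Retn (resistin) at 1.05 ± 0.25, Cidec at 1.27 ± 0.39 and Plin1 at 1.60 ± 0.56 (SE), the latter pair being lipid droplet proteins. Without doxorubicin 2, Cidec was at 0.78 and Plin1 at 0.81. Retn passed over the list alone (adjusted p = 0.0276 in edgeR). The call was lost without vehicle 2, vehicle 4, doxorubicin 2 or doxorubicin 4. It was also lost with library size as the only scaling, the marrow covariate or the replicate number as a block. Cidec passed with Retn without vehicle 1, as did Cidec and Plin1 without doxorubicin 3. The adipocyte list had an adjusted p of 0.000272 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation. All 17 skeletal muscle genes were above 0 (median 0.38), with Myl1 at 0.54 ± 0.48 (SE), 0.19 without vehicle 3 and 0.27 without doxorubicin 1. The adjusted p was 0.00774 with the preset correlation, and the adjusted p was 0.711 with an estimated correlation. That correlation between members was estimated at 0.95. The muscle score had an exact permutation p of 0.6 before adjustment over the lists. Without vehicle 3, the library with the least muscle RNA, the muscle list pointed lower (0.713), and the call was also lost without doxorubicin 1 (0.285) or doxorubicin 4 (0.116) and with the marrow covariate (0.354). Fibroblast and periosteum genes had a median of 0.20, with Clec3b at 0.97 ± 0.32 (SE), 0.63 without doxorubicin 1. Their adjusted p was 0.0470 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation; it was 0.0924 without vehicle 3, 0.163 without vehicle 4, 0.987 without doxorubicin 1, 0.0548 with the 1 CPM filter, 0.434 with the marrow covariate and 0.304 with the muscle covariate.

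Immediate early genes, which respond to handling, had a median of −0.34. Egr1 was at 61.2 ± 66.1 CPM in vehicle and 17.9 ± 10.7 CPM in doxorubicin bones, and Egr3 at 44.0 ± 44.5 and 12.9 ± 5.29 CPM (SD, n = 4 each). Both had a log2 difference of −1.77, which without vehicle 1 was −0.78 for Egr1 and −0.88 for Egr3. The adjusted p was 0.00193 with the preset correlation, and the adjusted p was 0.697 with an estimated correlation; it was 0.357 without vehicle 1, 0.0851 without doxorubicin 3 and 0.0599 without doxorubicin 4. Circadian genes had a median of 0.15, with the clock output gene Dbp at 0.69 ± 0.27 (SE), 0.44 without doxorubicin 4. Their adjusted p was 0.0472 with the preset correlation, and the adjusted p was 0.707 with an estimated correlation; it was 0.579 without vehicle 3, 0.558 without doxorubicin 1, 0.125 without doxorubicin 2, 0.0589 without doxorubicin 4, 0.0545 with library size as the only scaling, 0.0551 with the 1 CPM filter, 0.806 with the marrow covariate and 0.606 with the muscle covariate. The oxidative stress list had an adjusted p of 0.0694 and a median of −0.035, with 8 members above and 10 below 0. The cystine transporter Slc7a11 was at −1.27 ± 0.33 and Gclc, which acts in glutathione synthesis, at −0.35 ± 0.13 (SE). The list passed, on the lower side, without vehicle 1 (0.0425), vehicle 3 (0.0360) or doxorubicin 3 (0.0171). Its mean score differed by −0.11, with an exact permutation p of 0.0286 before adjustment over the lists. Stromal progenitor genes had an adjusted p of 0.751, with Angpt1 at −0.61 ± 0.20 and Ly6a at 0.57 ± 0.19 (SE). The adjusted p was 0.227 for endothelial, 0.752 for nerve and Schwann cell, 0.0733 for hypoxia and glycolysis and 0.374 for mitochondrial mRNA genes. The endothelial list passed without doxorubicin 2 (0.00106), the hypoxia list without vehicle 1 (0.0171), vehicle 2 (0.00801) or doxorubicin 2 (0.0355), with library size as the only scaling (0.0421) and with no filter (0.0344), and the mitochondrial list without vehicle 2 (0.00131) or doxorubicin 3 (0.00487). For TGF-beta and BMP genes it was 0.690, with a median of 0.05 and a mean of −0.01. In all, 9 lists were higher and 7 lower of the 35 with the preset correlation, 0 with an estimated correlation and 0 in fry, which does not compare a list with other genes; without doxorubicin 1 the number higher was 4.

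In the mouse build GRCm38, as given by the GENCODE M21 reference annotation (not stated to be the authors' own), Cyp2e1 (ENSMUSG00000025479.9) spans 140763739 to 140774987 on chromosome 7. Cfd (ENSMUSG00000061780.6) spans 79890853 to 79892655 on chromosome 10. Gp6 (ENSMUSG00000078810.4) lies at 4363965 to 4397744 on chromosome 7, Slamf1 (ENSMUSG00000015316.11) at 171767127 to 171801184 on chromosome 1 and Cd163 (ENSMUSG00000008845.9) at 124304656 to 124330527 on chromosome 6. The C3 gene (ENSMUSG00000024164.15) lies at 57203970 to 57228136 on chromosome 17. How reads were assigned over the exons of each gene is not given in the sources used here.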

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

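Each group of 4 libraries was searched for a library far from the other 3, over the named genes, the list scores and the library measures. Of 252 groups of values, 18 held one, where chance gives about 12.6. Vehicle 3 stood apart in skeletal muscle RNA, with a muscle list score of 8.32 against 10.58 to 10.70 (mean log2 CPM) and a muscle share of 0.733% against 3.26% to 3.57% in the rest of its group. Vehicle 3 was also apart in the plasma cell score (4.32 against 3.71 to 3.81), in Phlda3 (3.95 against 5.16 to 5.30 log2 CPM) and in Il1a (3.64 against 3.01 to 3.09 log2 CPM). Doxorubicin 1 was apart in the fibroblast and periosteum score (5.60 against 4.79 to 4.90), and lower in C5ar1 (4.25 against 4.47 to 4.51), Itgb3 (7.47 against 7.92 to 7.97), Treml1 (4.43 against 4.98 to 5.05) and Tubb1 (5.45 against 5.88 to 5.95 log2 CPM).

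Doxorubicin 2 was apart in the score of the secretory list (3.91 against 3.73 to 3.75), in Csf1 (6.10 against 5.45 to 5.51 log2 CPM) and in Mmp3 (−0.39 against 0.26 to 0.33 log2 CPM). Doxorubicin 4 was apart in Oscar (2.55 against 2.85 to 2.88), Hey1 (2.56 against 2.98 to 3.03) and Dbp (5.24 against 4.36 to 4.50 log2 CPM). Vehicle 2 was low in Dcstamp (1.18 against 2.39 to 2.5 log2 CPM), and vehicle 1 was high in Mmp3 (−0.16 against −0.92 to −0.79 log2 CPM).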

How the results depend on the processing

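Leaving out mitochondrial genes, the muscle covariate and the permutation of list scores were chosen after seeing the data. The count of genes past the threshold in edgeR was 0 higher and 0 lower in every alternative except no filter on low counts (1 higher) and DESeq2 (7 higher, 22 lower), and with each library left out in turn. Of 699 list values under the alternatives, 568 kept their side of the threshold, 97 lay short of it where the main test had passed, 31 gained it and 3 changed direction while past it on one side. These counts include fry and the exact permutation, which do not compare a list with other genes, so a value short of the threshold there is not a loss of the same test. The direction of lists changed in 40 values, and the sign of named genes in 16 of 1589, over 10 genes that passed no threshold in edgeR. The megakaryocyte, erythroid, interferon, MHC class II, cartilage and adipocyte calls held under each scaling, filter and covariate and with each library left out, except that the marrow covariate holds the erythroid score itself and so tests nothing for that list. All 6 lay short of the threshold with an estimated correlation (adjusted p 0.317 for megakaryocyte genes and 0.697 for the rest), in fry (between 0.344 and 0.701) and in the exact permutation (between 0.5 and 0.643). The cause of the losses below was not tested, except that an estimated correlation weighs how members vary together.

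The secretory list had an adjusted p of 0.0559 without haemoglobin genes, 0.0516 with the 1 CPM filter, 0.0639 without mitochondrial genes, 0.175 with the muscle covariate, 0.697 with an estimated correlation, 0.701 in fry and 0.643 in the exact permutation. The osteoblast list had 0.678 with the marrow covariate, 0.0582 with the muscle covariate, 0.711 with an estimated correlation, 0.713 in fry and 0.75 in the exact permutation. The osteoclast list had 0.697, 0.645 and 0.643 in the last 3. The monocyte and macrophage list had 0.0707 with the 1 CPM filter, 0.671 with the marrow covariate, 0.588 with the muscle covariate, and 0.707, 0.713 and 0.684 in the last 3. Lists past the threshold numbered 5 higher with the marrow covariate, 5 higher and 4 lower with the muscle covariate, and 0 higher and 0 lower with an estimated correlation, in fry and in the exact permutation. The neutrophil list turned higher with the marrow covariate (0.0407), which holds the neutrophil score itself, and the muscle list turned lower with the muscle covariate (0.588), which is the muscle score itself, and without vehicle 3 (0.713).

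With each library left out in turn, the adjusted p ranged from 0.0181 to 0.997 for complement components, 0.00801 to 0.289 for the secretory list, 2.8e-06 to 0.779 for osteoblast, 0.0407 to 0.939 for osteocyte, 1.8e-05 to 0.0528 for osteoclast, 0.0133 to 0.561 for osteoclast regulator, 0.00504 to 0.779 for monocyte and macrophage and 2.6e-05 to 0.713 for muscle genes. Between 4 and 10 lists were then higher. Whether replicate numbers pair the samples was not settled. Deviations of the same number correlated at 0.34, −0.27, 0.43 and 0.09. Libraries numbered 1 and 3 correlated best with their own number in both groups, as did vehicle 4. Vehicle 2 correlated best with doxorubicin 1, doxorubicin 2 with vehicle 3 and doxorubicin 4 with vehicle 2. With the replicate number as a block, 0 genes were higher and 0 lower (1466 at an unadjusted p under 0.05, against 913 without it and between 621 and 1784 with 1 library left out), and the monocyte and macrophage list had 0.0650, while B lymphoid (0.0437), T and NK cell (0.0366), oxidative stress (0.0335) and hypoxia (0.0335) lists passed. Over the lists alone, Cfd and Cd163 were not called with the block, Plin4 was called in place of Retn, and all 11 megakaryocyte genes were called, against 8 without it.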

Other observations

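Of the 29 genes that DESeq2 placed past its threshold, those given here lie outside the naming rule and were chosen after their values were seen; no enrichment was tested. Tubb1, the tubulin of platelets, was at 98.9 ± 15.0 CPM in vehicle and 55.9 ± 8.23 CPM in doxorubicin bones, and Mmrn1, a platelet and endothelial secreted protein, at 130 ± 30.6 and 74.8 ± 11.3 CPM (SD, n = 4 each). The laminin receptor subunit Itga6 was at 122 ± 15.3 and 75.8 ± 7.16 CPM, and Pde5a, which breaks down cyclic GMP, at 121 ± 20.9 and 74.4 ± 7.42 CPM (SD, n = 4 each). Their adjusted p was 0.00209, 0.0383, 0.00209 and 0.0167 in DESeq2 and between 0.698 and 0.703 in edgeR. Timd4, a receptor of resident macrophages for phosphatidylserine, was at 1.84 ± 0.848 and 0.451 ± 0.130 CPM, Atp8a1 at 179 ± 8.30 and 130 ± 7.13 CPM and Ccdc148 at 2.84 ± 0.690 and 1.09 ± 0.216 CPM (SD, n = 4 each). On the higher side were Eps8l1 at 7.56 ± 1.94 and 15.1 ± 2.06 CPM, Cilp, a cartilage matrix gene, at 10.1 ± 1.65 and 20.6 ± 6.15 CPM, and Hey1, a Notch target, at 4.46 ± 0.652 and 7.40 ± 1.06 CPM (SD, n = 4 each).

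The fat test for Cyp2e1, the count of intestinal genes with few counts elsewhere, the muscle RNA test of the megakaryocyte list and the splits for the edgeR count were tests chosen only after the result was seen; in the fat test the condition on 4 fat-cell genes was added after the list quartile, which alone would have counted against fat. The edgeR count was 0, so all 35 splits of the 8 libraries had to give at least as many (highest other 0), and that test says nothing. Chance could not be excluded for the DESeq2 count or the number of lists. In DESeq2 8 splits, the real grouping included, gave at least 29 genes. The highest other gave 857, for vehicle 1 and 4 with doxorubicin 1 and 2 against the rest. In edgeR that split gave 0 genes, and what sets its libraries apart was not tested. For gene lists with the preset correlation 14 splits, the real grouping included, gave at least 16, the highest other 21.

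The lower megakaryocyte list was weighed against chance, residual marrow, scaling and muscle. In 2 of the 35 splits, the real grouping included, the camera p was as small as the real 5.0e-17, so chance was not excluded. The other split, at 1.2e-18, set vehicle 1 with doxorubicin 1, 3 and 4 against the rest. Less marrow left in the doxorubicin bones predicts an equal fall of the other marrow lists. The megakaryocyte score minus the mean of the neutrophil, erythroid, B lymphoid and progenitor scores was also lower, by −0.42. Its exact permutation p was 0.0286, the smallest possible. The list was singled out by its camera p, and its score alone already had this permutation p. The p of the difference was not adjusted for that choice, so it cannot by itself exclude less marrow. Taken 1 by 1, the exact permutation p was 0.0286 against the progenitor, monocyte and macrophage, and endothelial scores and 0.0571 against T and NK cells. It was 0.114 against B lymphoid, 0.143 against neutrophil and plasma cell and 0.514 against erythroid scores, so an uneven loss of marrow cells may remain. Another scaling moves all genes alike, so the gap of the list median to that of all genes, −0.58 and at the smallest −0.57 over 4 other scalings, tests nothing, while with the muscle covariate it was −0.48, which argues against muscle RNA as the whole cause. An effect of doxorubicin on megakaryocytes themselves was not tested and stays open.

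Cyp2e1 was weighed against fat, liver RNA and shared reads. Alb, one of the most abundant liver transcripts, was at 0.0543 CPM in the doxorubicin libraries against 4.51 CPM for Cyp2e1 and 0.0845 CPM in vehicle, which argues against liver RNA, although Serpina1a had a log2 fold change of 1.43 and Apoa1, also an intestinal gene, was at 0.0328 CPM in vehicle and 1.67 CPM in doxorubicin. For fat, the upper quartile of the adipocyte log2 fold changes was 0.83, below the lower bound of 1.38 for Cyp2e1, but other bone cells express much of that list. Of the 4 genes taken as most specific to fat cells (Plin1, Cidec, Retn and Lep), 3 did not differ from Cyp2e1 beyond the bound set. That bound was a multiple of the combined SE of both genes. The 3 were Plin1, Cidec and Lep, while Retn did differ. The condition is loose, since a gene with a large SE meets it easily. Plin1, at 1.60, lay above the lower bound of 1.38 for Cyp2e1, while Cidec (1.27) and Retn (1.05) lay below it. Adipoq, a fat-cell gene that was not among the 4, had a log2 difference of −0.02, so fat-cell genes did not rise alike. More fat may be part of the Cyp2e1 difference and cannot be told apart from a change within cells. Of 9 other tested Cyp2 genes, 8 had log2 fold changes between −0.32 and 0.54, below the bound of 1.38. Cyp2f2 alone lay above it at 1.72, so shared reads stay open.

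For the interferon list 6 of the 35 splits, the real grouping included, had a camera p as small as the real 4.2e-11 (smallest other 7.6e-38). Without doxorubicin 3, 0.563 of the group difference in mean score was kept. Doxorubicin 1 held 196 counts of Apoa4, 51 of Sis and 50 of Fabp2, genes of the intestinal lining, against at most 5, 4 and 2 in any other library, and these were named after their values were seen. The summed CPM of 10 other intestinal genes, fixed before that test, was 1.48 times the highest other library, but Lgals4, Muc13 and Mttp gave between 52 and 690 counts in every library and hid a small share; the sum, which lay under the bound of 2 set beforehand for no intestinal RNA, was set aside for that reason only after it was seen. Of the 7 with at most 10 counts in each other library, 6 were over 2 times the highest other in doxorubicin 1, Apob with 259 counts against 4, which is consistent with a trace of intestinal RNA in that library; no biological explanation was tested.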
